A study of Mus musculus with 22 samples.

How the data were processed

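Forelimbs of mouse embryos at embryonic day 13.5 were profiled, 9 wild-type and 13 Chsy1 knockout samples. Per the labels' protocols, total RNA was amplified, labelled with Cy5 and hybridised against a Cy3-labelled universal mouse reference RNA. Groups and replicate numbers came from the sample labels. Spots were quantified with Agilent Feature Extraction 9.5, per the submitters' processing notes, and version 9.5.3.1, per the file headers. Per the file headers, the deposited spot and background brightness values are raw intensities, and the processed signal intensities were background-subtracted and dye-normalised by that software. The deposited ratio of each spot is the log10 of processed Cy5 over processed Cy3. The deposited value table holds the same log10 ratios: it differed by 0 from the scanner ratio in each of the 22 arrays, and each column's median was 0. Its scale and direction are thus those of the scanner ratio. The medians were taken over all spots, controls included, so they do not show how the values were centred. The flags for outliers, saturation and signal above background are deposited as 0 or 1. No sample-level column was without a sample.

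From these files, mean spot intensities were corrected with normexp (offset 50) against the background medians and normalised by loess within each array, with control and outlier spots at weight 0. Control spots and outlier spots were then left out, and spots of 1 probe were averaged, giving 41174 probes. No non-control spot was saturated. A probe was tested if its Cy5 signal was well above background on at least 9 arrays, which 27803 probes were. Names were updated through a reference table of GRCm38.p6, used only for names and gene order. The probe's accession matched for 23374 probes and another listed accession for 103, while 6678 carried a current symbol and 2891 an older one. For 1644 the name of the array design was kept, and 6484 had no gene name and stood for themselves. Each gene was represented by its probe with the highest mean intensity, leaving 18654 genes and unnamed probes, of which 16079 were named. Probe coordinates are those of the files, on mm8, for which no annotation was used here.

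Differences, knockout minus wild type, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 22 arrays without covariates. Adjusted p-values are Benjamini-Hochberg over all tested genes at a threshold of 0.05, and intervals are 95%. The 36 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The 26 missing gene values were filled with fitted values for the list tests only. The named genes were 15 key genes, the called genes (up to 10 in each direction), up to 4 passing members of each list or its member with the smallest p, and the 5 nearest measured genes on each side of Chsy1. The groups, the fits, the lists, this rule and the settings to be compared were fixed before the data were examined.

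The fit was tested on simulated data with known changes in 18654 genes. With 200 changed genes it recovered 32% of 1.2-fold, 91.2% of 1.5-fold, 99.2% of 2-fold and 99.6% of 4-fold changes, with 4.73% false calls. With 20 changed genes it recovered 4%, 72%, 96% and 100%, with 4.05% false calls. The 20 were shared among all fold sizes in each of 5 simulations, so these rates are rough. This smaller setting was added after the real count was seen. A list shifted by 0.3 was called in 5 of 5 simulations in both settings, and other lists were called 1 and 0 times. In every simulation the genes of that list were shifted besides the changed genes. The simulated values hold no correlation between genes, so they do not test the false calls of lists on real arrays. Changes were added after normalisation, so compression of ratios by the offset and arrays that stand apart were not simulated.

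Alternatives covered background correction, within-array and between-array normalisation, the Cy5 channel alone, the deposited value table, the probe filter, averaging of probes, blocks for slide and replicate number, array weights, the variance model and leaving out each of the 22 arrays. Another 6 were added after seeing the data, namely position on the slide as a block, the 6 arrays of position 2, the same without knockout 1, a Y-linked covariate, and 2 omissions of array pairs. All arrays were scanned on 1 day. No pair of arrays held identical values, with correlations across genes from 0.886 to 0.993.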

Results

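Gene expression was measured in mouse forelimbs at embryonic day 13.5 from animals with and without Chsy1, which encodes chondroitin sulfate synthase 1, an enzyme that extends the chondroitin sulfate chains of proteoglycans. Total RNA of each sample was labelled with Cy5 and hybridised on a two-colour oligonucleotide array against 1 Cy3-labelled universal mouse reference RNA, so every value is a log2 ratio of sample to reference and no dyes were swapped. The series holds 22 arrays, of which 9 are wild type and 13 are knockout. Between 27214 and 30599 of 43379 non-control spots per array had a Cy5 signal well above background, and the median Cy5 signal lay between 102.8 and 178.9 units against a median background of 54 to 57. The design text calls the samples biological replicates, but the labels do not say whether each is 1 embryo or a pool, so the p-values measure only the spread between these samples. The number of arrays limits the precision. The arrays sat on 6 slides that all held both genotypes. Positions on the slide were less balanced: position 1 held 6 wild-type arrays, position 2 held 3 wild-type and 3 knockout arrays, and positions 3 and 4 held 6 and 4 knockout arrays.

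The single comparison asks how forelimb expression differs when Chsy1 is missing. Chsy1 itself was measured first, because it checks the labels. Its 1 probe (chromosome 7, 66052663 to 66052722, on the mm8 coordinates of the files) had a mean log2 ratio of 1.73 ± 0.28 (SD, n = 9) in wild type and -4.38 ± 1.39 (SD, n = 13) in knockout. The difference was -6.11 (SE 0.44, 95% interval -7.02 to -5.21), with an adjusted p of 1.29e-08 in limma. In 12 of the 13 knockout arrays the ratio of sample to reference was between 0.869% and 1.82% of the wild-type mean, taken on the log2 scale. These spots were still well above background, at 115.6 to 267.5 units, but the added offset compresses ratios at such signals. The array labelled knockout 1 was different: its log2 ratio was 0.15, which is 33.6% of the wild-type mean. Without this array the difference was -6.49. Chsy1 was lower in the knockout arrays of all 6 slides, by log2 -6.67 to -4.94, and within position 2 the difference was -4.66. Knockout 1 is in the slide at -4.94 and in position 2, and without it the slides ran from -6.69 to -6.20 and the difference within position 2 was -6.15. The labels do not state which part of the gene was altered.

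**Figure D1:**
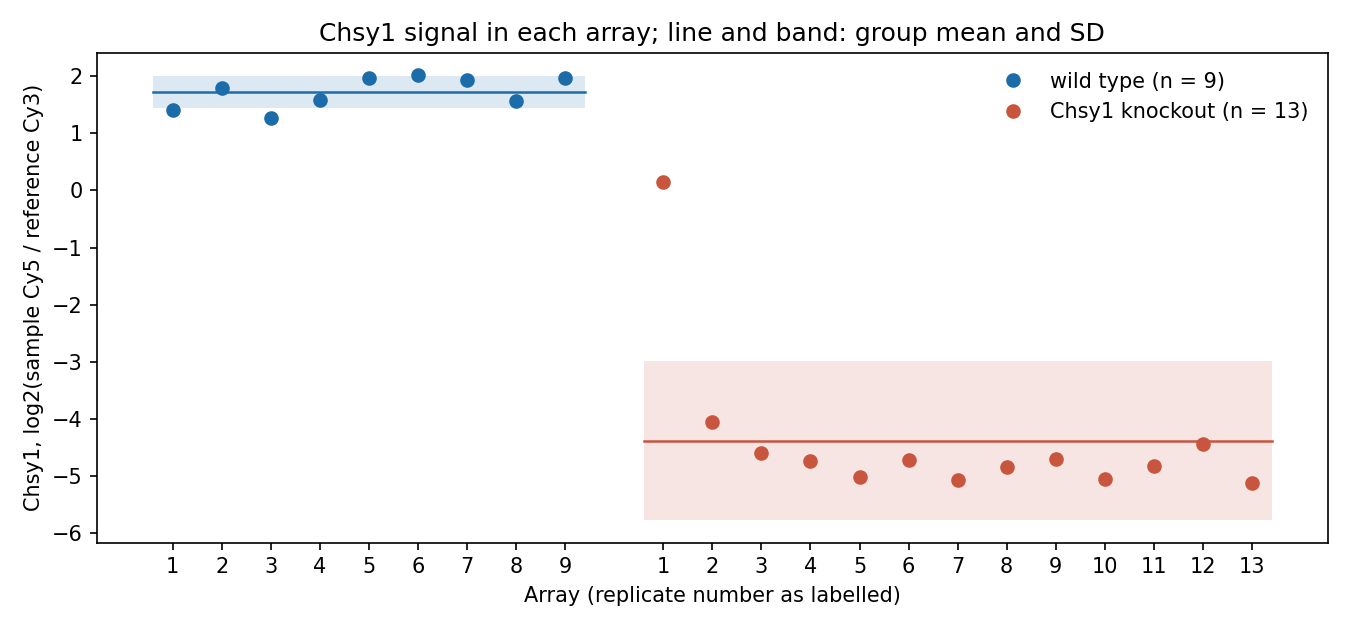
Chsy1 log2 ratio of sample to reference (y axis) for each array (x axis, replicate number as labelled), with points for single arrays and a line and band for the mean and SD of each group. The 9 wild-type arrays lie between 1.28 and 2.02, 12 knockout arrays lie between -5.12 and -4.05, and the array labelled knockout 1 lies at 0.15.

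Beyond Chsy1, few genes differed between the forelimbs of the 2 genotypes at the threshold. Of 18654 genes tested with limma, 4 passed an adjusted p of 0.05, and all 4 were lower in knockout. The other 3 changed by small amounts. Grb14, an adaptor protein that binds the insulin receptor, fell by 0.40 on the log2 scale (SE 0.063, adjusted p = 0.015, 1.32-fold). Ptx3, a secreted pentraxin of innate immunity and hyaluronan-rich matrix, fell by 0.39 (SE 0.066, adjusted p = 0.026, 1.31-fold). Pcolce2, which enhances the processing of procollagen, fell by 0.35 (SE 0.058, adjusted p = 0.019, 1.28-fold). All 13 knockout arrays lay below the wild-type median for each of these 3 genes. The files place the probe of Grb14 at chromosome 2, 64713502 to 64713561, that of Ptx3 at chromosome 3, 66313207 to 66313266, and that of Pcolce2 at chromosome 9, 95504369 to 95504428. A second Ptx3 probe gave a log2 difference of -0.35, while a second Grb14 probe was not well above background on any array. No gene was higher in knockout at the threshold, where 257 genes had an unadjusted p under 0.05 in that direction and 737 in the other, 994 in all against 932.7 that chance gives. The 95% interval lay within 1.5-fold in either direction for 96.6% of the genes. These intervals are on ratios that the added offset compresses at low signals. They therefore do not bound the RNA differences of dim genes. The same fit was run on data simulated for this comparison with 18654 genes, of which 20 were changed besides a shifted list. It recovered 72% of 1.5-fold changes and 4% of 1.2-fold changes. The 20 genes were shared among all fold sizes in each of 5 simulations, so these rates are rough. Those changes were added to normalised ratios, so the rates leave out compression by the offset and arrays that stand apart.

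The 3 small falls were lower in knockout on each of the 6 slides (Grb14 -0.54 to -0.09, Ptx3 -0.68 to -0.14, Pcolce2 -0.48 to -0.20) and within position 2 (-0.37, -0.37 and -0.26). Their calls are close to the threshold: with the slide as a block the adjusted p was 0.14 for Grb14, 0.24 for Pcolce2 and 0.065 for Ptx3, and only Chsy1 passed. Leaving out wild-type 2, 5 or 6 left 2 genes, Chsy1 and Grb14, and ended the call of Pcolce2, with adjusted p of 0.054, 0.053 and 0.051, and 12 of the 22 omissions ended that of Ptx3, with adjusted p up to 0.092. Without wild-type 1 and knockout 12, which stood apart on a principal component, Chsy1 alone passed. Without knockout 1 and wild-type 8 the count was 5. Both pairs were chosen after seeing the data. Leaving out knockout 1 alone gave 3 genes and ended the call of Ptx3 (limma adjusted p = 0.060), while leaving out wild-type 8 alone gave 6. Median centring in place of loess moved the median of all genes to 0.24, and relative to it Grb14, Ptx3 and Pcolce2 differed by -0.35, -0.30 and -0.30, with Chsy1 alone past the threshold. Chsy1 alone also passed with the scanner software's log ratio and with position on the slide as a block.

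Other genes of chondroitin sulfate synthesis did not pass the test. Csgalnact1, which starts the chondroitin chain, differed by -0.36 (95% interval -0.62 to -0.10, adjusted p = 0.91). Chsy3, a second chondroitin synthase, differed by 0.17 (-0.11 to 0.46; 0.18 and -0.0097 by other probes), and the polymerising factor Chpf by -0.14 (-0.29 to 0.02). Among signals of the limb, the joint factor Gdf5 differed by 0.09 (-0.23 to 0.40) and Ihh, the hedgehog ligand of growing cartilage, by -0.13 (-0.37 to 0.12). The hedgehog targets Ptch1, Gli1 and Hhip differed by -0.09 (-0.23 to 0.05), -0.08 (-0.36 to 0.20) and -0.25 (-0.57 to 0.07; -0.029 by another Hhip probe), and Bmp2 by 0.06 (-0.41 to 0.53). Of the cartilage genes, the type II collagen gene Col2a1 differed by -0.10 (-0.31 to 0.11), the aggrecan gene Acan by -0.22 (-0.59 to 0.14) and the chondrocyte regulator Sox9 by 0.00085 (-0.25 to 0.25; 0.21 and 0.09 by other probes). Each of these intervals except that of Csgalnact1 includes 0, but several values rest on wild-type 1, on the position or on the normalisation. In position 2 without knockout 1, Csgalnact1 differed by -0.0024, Col2a1 by -0.31, Acan by -0.62 and Gli1 by -0.44, and Chsy1 alone passed. Without wild-type 1, Acan differed by -0.39 (-0.66 to -0.11), Hhip by -0.39 (-0.64 to -0.14), Gli1 by -0.18, Ihh by -0.20 and Chsy3 by 0.06, while Bmp2 (-0.14), Gdf5 (-0.018) and Sox9 (-0.0096) changed sign, and none of these passed over all genes. With the scanner software's log ratio, Ptch1 differed by -0.40 (-0.78 to -0.028), Gli1 by -0.30, Hhip by -0.56 and Ihh by -0.35, Bmp2 (-0.013), Gdf5 (-0.078) and Sox9 (-0.013) changed sign, and none of these passed either. With median centring, relative to the median of all genes, Col2a1 differed by 0.0069, Bmp2 by -0.015, Gdf5 by 0.18, Sox9 by 0.11, Ptch1 by -0.37, Gli1 by -0.31, Hhip by -0.42 and Ihh by -0.34. Shh was well above background on 2 knockout arrays and no wild-type array, and Col10a1 on 3 arrays of each group, so neither was tested. The 10 measured genes nearest to Chsy1 in the reference gene order (Tarsl2, Tm2d3, Pcsk6, Snrpa1 and Selenos on one side, Lrrk1, Aldh1a3, Asb7, Lins1 and Lysmd4 on the other) had log2 differences from -0.16 in Lrrk1 (-0.33 and -0.10 by other probes) to 0.23 in Aldh1a3 (0.037 by another probe; 0.05 without wild-type 1), and none passed the test.

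**Figure D2:**
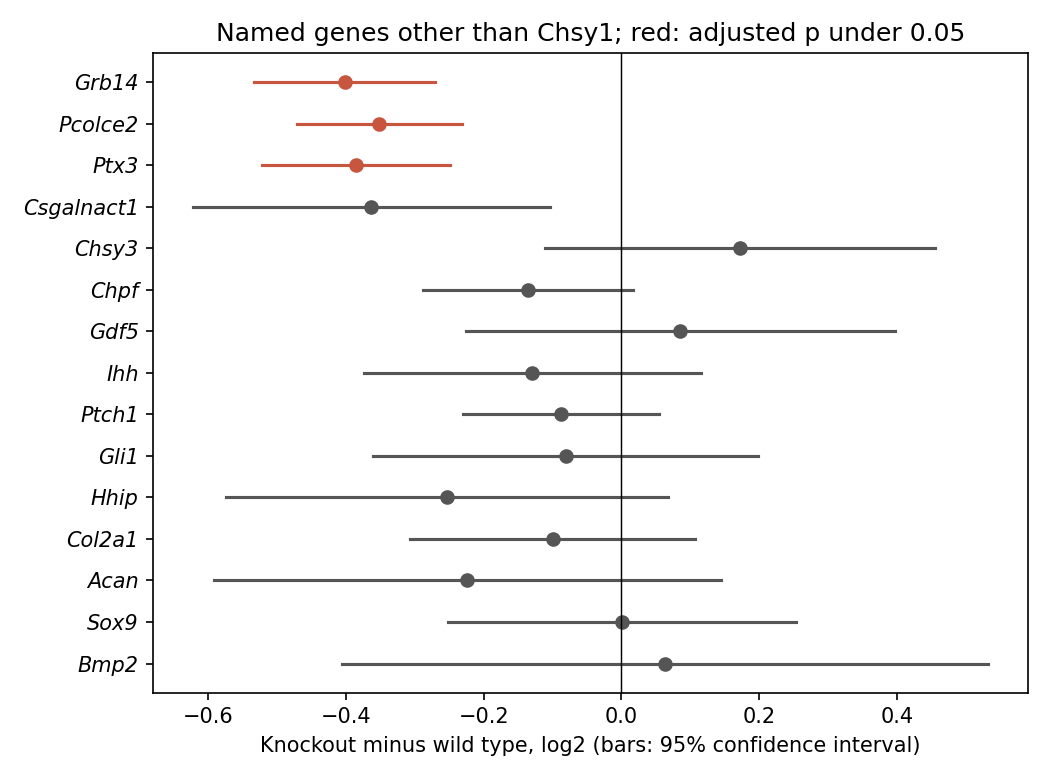
Difference between knockout and wild type (x axis, log2) for 15 named genes (y axis), with points for the estimate and bars for the 95% confidence interval. Grb14, Pcolce2 and Ptx3, in red, passed an adjusted p of 0.05 and lie between -0.40 and -0.35.

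Genes were then read as 36 lists fixed in advance. With camera at its preset correlation, 10 lists passed an adjusted p of 0.05, of which 7 were shifted down and 3 up in knockout. None of the 10 passed with an estimated correlation, and 37 of 100 splits of the 22 arrays into groups of the same sizes, the real one included, gave at least as many lists. The median shifts were small, from -0.18 to 0.11 on the log2 scale.

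In the hypertrophic cartilage list, 11 of 12 tested genes were lower (median -0.18, camera adjusted p = 0.0022, adjusted p = 0.37 with an estimated correlation). None passed over all genes, and 2 passed adjusted over the list alone, Alpl and Runx3, the latter named after its value was seen. Alpl, the alkaline phosphatase of mineralising tissue, differed by -0.44 (95% interval -0.73 to -0.15). In the osteoblast list, 13 of 16 were lower (median -0.11, adjusted p = 0.0039, adjusted p = 0.66 with an estimated correlation), with 2 adjusted over the list alone, Alpl and Smpd3. Smpd3, a sphingomyelinase needed for bone mineralisation, differed by -0.58 (-0.90 to -0.25; -0.69 and -0.22 by other probes). This call ended without wild-type 5. The lists share Alpl and several other genes. In the skeletal muscle list 21 of 25 were lower (median -0.13, adjusted p = 0.0037, adjusted p = 0.73 with an estimated correlation), and its member with the smallest p, the skeletal actin gene Acta1, differed by -0.29 (-0.57 to -0.0071). In the list of fibrillar collagen and fibronectin matrix 16 of 18 were lower (median -0.12, adjusted p = 0.012, adjusted p = 0.73 with an estimated correlation), with Tnc, which encodes tenascin C, at -0.24 (-0.13 and -0.034 by other probes). That call ended without any 1 of wild-type 5, 7 and 9 and knockout 1 and 12.

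The chondroitin sulfate synthesis list was shifted down with 21 of 30 lower (median -0.03, adjusted p = 0.012, adjusted p = 0.69 with an estimated correlation), but it contains Chsy1. Without Chsy1 its 29 other genes had an adjusted p of 0.13, and with Chsy1 the call ended without any 1 of wild-type 5, 6 and 9. In the interferon response list 12 of 13 were lower (median -0.16, adjusted p = 0.0039, adjusted p = 0.73 with an estimated correlation), with the RNA sensor gene Ddx58 at -0.38 (-0.12 and -0.10 by other probes). In the immediate early list 10 of 12 were lower (median -0.16, adjusted p = 0.021, adjusted p = 0.73 with an estimated correlation), with 2 adjusted over the list alone, Atf3 at -0.23 and Jun, the latter named after its value was seen.

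The lists shifted up were limb patterning, Notch and bone morphogenetic protein. In the limb patterning list 26 of 32 were higher (median 0.11, adjusted p = 0.0022, adjusted p = 0.73 with an estimated correlation), with the homeobox gene Prrx2 at 0.30 (0.11 to 0.48). In the Notch pathway list 14 of 19 were higher (median 0.10, adjusted p = 0.0039, adjusted p = 0.66 with an estimated correlation), with 1 adjusted over the list alone, the receptor gene Notch3 at 0.25 (0.11 to 0.40). In the bone morphogenetic protein list 18 of 25 were higher (median 0.08, adjusted p = 0.016, adjusted p = 0.73 with an estimated correlation), with Id2 at 0.17 and, by a second probe, at -0.045. In wild-type 1 the means of these 3 lists, relative to all arrays, were -0.83, -0.49 and -0.49, and that of the interferon list was 0.78. Without this array the calls of these 3 lists and of the interferon and immediate early lists ended. The bone morphogenetic protein call also ended without wild-type 6, and the immediate early call without any 1 of wild-type 4 and 5 and knockout 1 and 5.

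**Figure D3:**
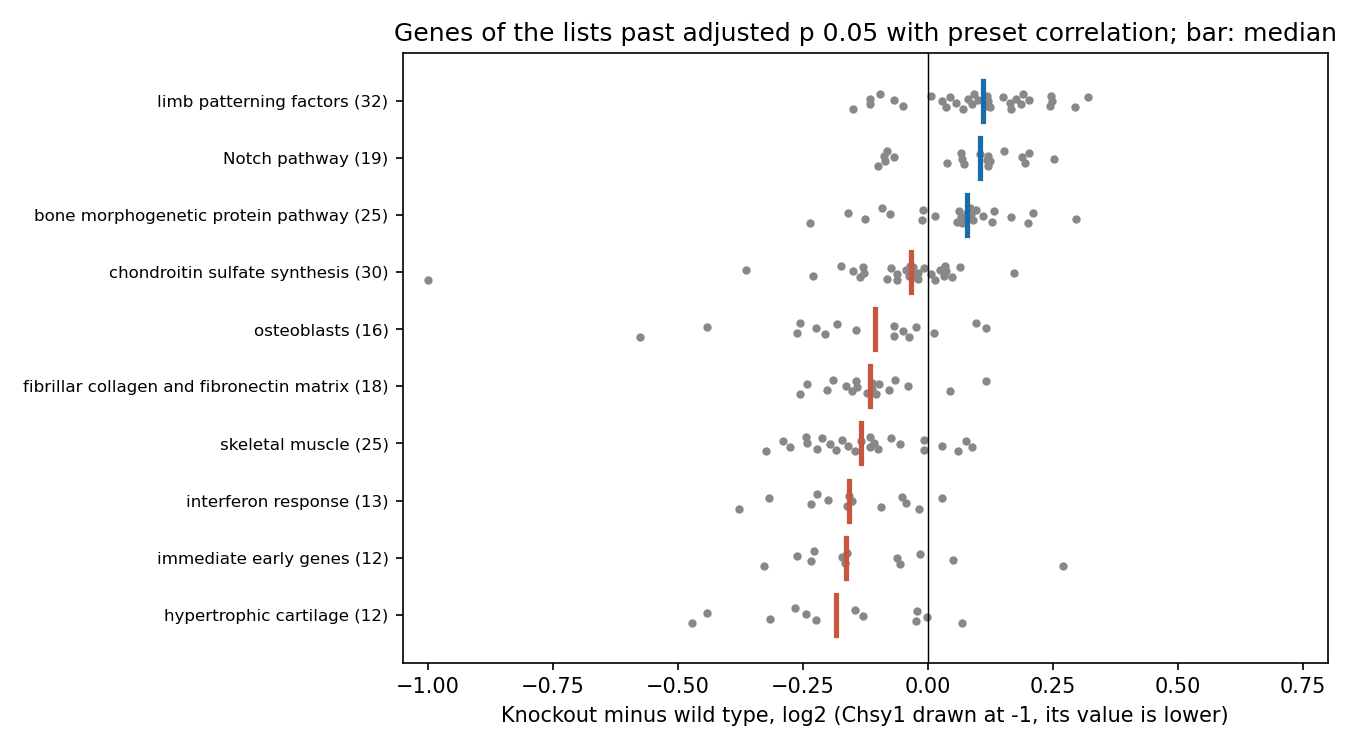
Difference between knockout and wild type (x axis, log2) for the genes (points) of the 10 lists (y axis, tested genes in parentheses) that passed with a preset correlation, with a bar at each median. The medians run from -0.18 in hypertrophic cartilage to 0.11 in limb patterning factors, and Chsy1 is drawn at the left edge because its value is lower.

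All 10 lists stayed past the threshold in their direction with the slide as a block. Within single slides their means kept that direction less often, on 3 to 6 of the 6 slides. Bone morphogenetic protein did so on 3, and skeletal muscle, the fibrillar matrix, interferon and immediate early lists on 4 each. With the position as a block, 4 of the 10 stayed past the threshold in their direction. These were skeletal muscle, osteoblasts, the fibrillar matrix and chondroitin sulfate synthesis, whose list still held Chsy1 in both fits. The position contrast rests on the 3 wild-type and 3 knockout arrays of position 2. Within it the medians of 4 of the 10 lists changed sign, to -0.02 for limb patterning, -0.03 for Notch, -0.08 for bone morphogenetic protein and 0.04 for the interferon response. Without wild-type 5, 6 lists passed. With the scanner software's log ratio 10 lists passed, of which 5 were among the 10 above, and with median centring 4 passed, of which 1 was.

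The remaining 26 lists did not pass with the preset correlation on all arrays. Without wild-type 1, 6 of them passed, all shifted down: cartilage matrix and chondrocyte regulators (median -0.15, camera adjusted p = 6.48e-06), endothelium (-0.13, 0.00066), tendon (-0.22, 0.0014), surface ectoderm (-0.11, 0.0042), the hedgehog pathway (-0.10, 0.035) and matrix remodelling enzymes (-0.07, 0.036). These 6 calls were not tested with an estimated correlation. Over 41 other settings, leave-outs included, the tendon list passed in 20, the cartilage list in 10 and the endothelium list in 9, each downward. Single omissions other than that of wild-type 1 also gave calls. Tendon passed without any 1 of wild-type 3 and 8 and knockout 4, 6, 7, 8, 9, 10 and 13, erythroid cells without any 1 of wild-type 3, 4 and 8 and knockout 2, 3, 7, 8 and 12, and lysosomal breakdown without any 1 of wild-type 2 and 3 and knockout 8, 9 and 10. Surface ectoderm passed without knockout 10, the Wnt pathway without knockout 12, and Schwann cells and neural crest without wild-type 3. The values that follow are those of all arrays. Among matrix and skeletal lists, the medians were -0.04 for cartilage matrix and chondrocyte regulators, -0.04 for proteoglycan core proteins, 0.0029 for heparan sulfate synthesis, -0.04 for hyaluronan metabolism, -0.08 for lysosomal glycosaminoglycan breakdown, -0.04 for matrix remodelling enzymes, 0.03 for the joint interzone and -0.19 for tendon (adjusted p = 0.062). Examples with the smallest p in their list were Sox5 at 0.34, Epyc at -0.83, Extl1 at -0.29, Cd44 at -0.19, Galns at -0.19, Plod2 at -0.14, Prg4 at 0.32 and Thbs2 at -0.24. Other probes gave 0.05 for Sox5, -0.70 for Epyc, -0.055 for Extl1 and -0.34 for Cd44. Thbs2 alone passed adjusted over the tendon list alone. Among signalling lists, the medians were -0.06 for hedgehog, 0.02 for transforming growth factor beta, 0.02 for Wnt, 0.0026 for fibroblast growth factor and -0.05 for retinoid metabolism. Ccn2 was the 1 gene adjusted over the transforming growth factor beta list alone, at -0.39. Frzb stood at 0.31 (0.17 without wild-type 1 and -0.067 with the scanner software's log ratio), Spry1 at 0.17 and Crabp1 at -0.24. Hindlimb factors had a median of 0.05, with Isl1 at 0.37 (0.21 without wild-type 1).

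Lists of other cell types in the limb had medians of -0.03 for endothelium, 0.0067 for macrophages, 0.04 for erythroid cells, -0.06 for surface ectoderm, 0.03 for Schwann cells and neural crest, 0.0076 for neurons and -0.06 for liver and other trunk tissue. Their members with the smallest p were Flt1 at -0.11 (0.08, -0.045 and -0.10 by other probes), Cd68 at -0.13, Epb42 at 0.15, Epcam at -0.13, Erbb3 at 0.15, Nefm at 0.46 (0.28 without wild-type 1) and Fgg at -0.08. Other probes gave 0.047 for Epb42 and 0.051 for Erbb3. The medians were 0.02 for cell cycle, 0.02 for hypoxia and glycolysis, -0.05 for the unfolded protein response and -0.03 for apoptosis, with Ccne1 at -0.15, Ldha at 0.20, Chac1 at -0.19 and Fas at -0.30. A second Ldha probe gave 0.12. Camera placed apoptosis up although its median and mean were below 0. The heparan sulfate and transforming growth factor beta lists had a median above 0 and a mean below it. With position as a block, the unfolded protein response was up (camera adjusted p = 0.00038), as were macrophages (0.017). Over the other settings, leave-outs included, each of these 2 lists passed upward in 3. Erythroid cells passed upward in 8 and downward in 1, and liver and other trunk tissue upward in 1 and downward in 1.

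Sex-linked transcripts differed between arrays of both groups. Xist, the transcript that silences an X chromosome in female cells, was well above background on 3 wild-type and 12 knockout arrays. It differed by 1.79 between knockout and wild type (95% interval -0.36 to 3.94). By 3 other probes it differed by 0.43 to 0.99, and with the scanner software's log ratio by 4.08 (0.87 to 7.29). The list of X inactivation and Y-linked genes had a median of -0.36 and did not pass. That list joins Xist with Y-linked genes, which go opposite ways with sex. Its directional test therefore cannot decide whether sex differed between the groups. In the array labelled knockout 1, Xist stood at 28.03% and the mean of Ddx3y, Eif2s3y and Kdm5d at 56.2% of the array where each was highest. In wild-type 8 these values were 79.5% and 21.6%. Xist stood at 55.9% to 100% of its highest array in wild-type 8 and 9 and knockout 2, 3, 5, 6, 12 and 13. The Y-linked mean in those arrays was 7.42% to 21.6%. In all other arrays but knockout 1, Xist was at 1.10% to 7.25% and the Y-linked mean at 52.1% to 100%. Arrays high in Xist thus made up a larger part of the knockout group than of the wild-type group. With the Y-linked mean as a covariate, Chsy1 alone passed, and Grb14, Ptx3 and Pcolce2 differed by -0.39, -0.38 and -0.33.

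**Figure D4:**
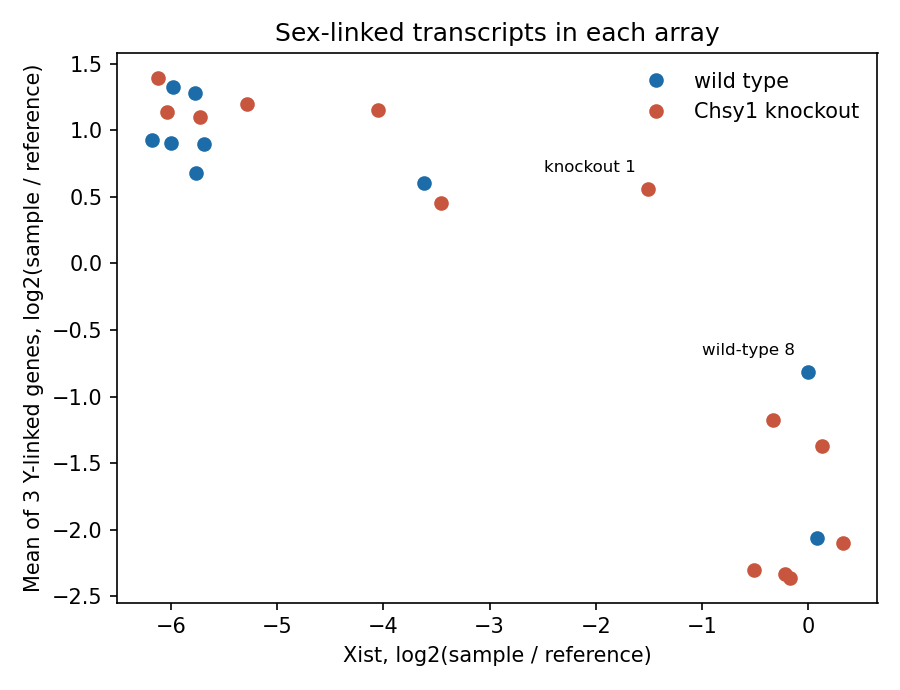
Mean log2 ratio of 3 Y-linked genes (y axis) against that of Xist (x axis) for each array, with points for single arrays coloured by group. The array labelled knockout 1 lies at -1.51 for Xist and 0.56 for the Y-linked genes, and wild-type 8 at -0.0041 and -0.82.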

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

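The comparison of the reference channel was added after the data were examined.

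Within the wild-type group of 9 arrays, 99 measures were examined for an array far from the others, and 21 had one. Chance gives about 1 in 20, and the measures overlap in genes, so these are not independent. Of the 21, 17 were in wild-type 1. The knockout group is too large for this rule.

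Wild-type 1 had low means, relative to all arrays on the log2 scale, for endothelium (-0.97), cartilage matrix and chondrocyte regulators (-0.93), limb patterning factors (-0.83), Schwann cells and neural crest (-0.76), the Wnt pathway (-0.66), the joint interzone (-0.63), neurons (-0.63) and skeletal muscle (-0.62). Its means were also low for the bone morphogenetic protein (-0.49), Notch (-0.49) and fibroblast growth factor (-0.45) pathways, retinoid metabolism (-0.37) and hyaluronan metabolism (-0.19). Its interferon response mean was high at 0.78, with the nearest other wild-type array at 0.22. Among single genes, its log2 ratios of Hhip (0.59), Bmp2 (0.74) and Frzb (1.77) were low.

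Other wild-type arrays stood apart in 1 measure each. These were Prrx2 in wild-type 6 (1.00), Flt1 in wild-type 8 (-1.29), Snrpa1 in wild-type 3 (-0.047) and the matrix remodelling mean in wild-type 5 (0.26).

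The reference channel holds the same RNA on every array and is the denominator of the log ratios, but its own signal was not compared between the groups elsewhere. In it, 1 gene passed an adjusted p of 0.05. It was Chsy1, whose Cy3 signal was higher by 0.12 on the log2 scale beside knockout samples (limma adjusted p = 0.0022). In this channel 848 genes had an unadjusted p under 0.05, fewer than the 932.7 that chance gives.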

How the results depend on the processing

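The position, Y-linked and array-pair settings were chosen after seeing the data. Chsy1 was lower under every setting and passed in all but 1: with the 6 arrays of position 2 alone it differed by -4.66 and 0 genes passed in limma (adjusted p = 1.00 for Chsy1, with 440 genes at an unadjusted p under 0.05). Position 2 holds knockout 1, and without that array Chsy1 differed by -6.15 and was the 1 gene that passed (over all settings its adjusted p ran from 6.3e-21 to 1.00), so that array accounts for the smaller difference and the lost call. Of 4 genes past the threshold, all lower, 1, which was Chsy1, remained with the scanner software's log ratio, the deposited value table, median centring, the slide block, the replicate block, the position block, the Y-linked covariate, and without wild-type 1 and knockout 12. Without background subtraction, 1 gene, Chst8, was higher. With the scanner software's processed signals 4 genes passed, with Plb1 in place of Ptx3, and 5 of the 10 lists were shared. Leaving out 1 array gave 2 genes (without wild-type 2, 5 or 6) to 6 (without wild-type 8). Aquantile leaves log ratios as they are, so it tests nothing. The 10 lists became 4 with median centring, 16 in position 2 alone, 0 with an estimated correlation, 0 with directional fry and 1 with mixed fry, and 6 (without wild-type 5) to 14 when 1 array was left out. With median centring the immediate early list turned (median 0.16, beside 0.24 for all genes, where 7216 genes had an unadjusted p under 0.05). With the position block and in position 2 alone, the bone morphogenetic protein (-0.080) and interferon (0.042) lists turned, and the medians of Notch (-0.025) and limb patterning (-0.024) changed sign. With that block the unfolded protein response list, down without a call on all arrays, was up and passed (camera adjusted p = 0.00038). In position 2 without knockout 1, the bone morphogenetic protein (-0.044), Notch (-0.059), limb patterning (-0.086) and interferon (0.073) lists turned. The values do not show that replicate numbers pair the samples, but they cannot exclude it. Of 9 same-numbered pairs, 3 had deviations correlated over 0.1, with a range of -0.31 to 0.49. Of the 9 wild-type arrays, 2 correlated best with their own number. The replicate block therefore only shows a count of 1. Scan date was not run, because all arrays share 1 day. For the other settings the cause was not tested. Over 41 settings, with Aquantile and the deposited value table (which repeats the scanner software's log ratio) not counted, 2305 named-gene values kept their call or moved by less than 1 SD between arrays, 67 moved further, 44 lost their call and 0 turned among genes with a call. Uncalled genes did change sign: 36 of the 60 named genes did so in at least 1 setting, 127 of 2457 values in all, 20 of them with median centring, which raises the median of all genes. Among the lists' values 1311 stayed, 59 lost a call, 95 gained one and 9 turned. In 12 knockout arrays the Chsy1 signal was 115.6 to 267.5 units, at which the added offset compresses ratios. Its difference was -6.11 as reported, -6.20 without background subtraction, and -7.02 with the scanner software's log ratio, which changes background and dye treatment together.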

Other observations

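Tests of sex and of position on the slide, and those of the array labelled knockout 1, were chosen after the results were seen; the others were planned.

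Wild-type 1 and knockout 12 had the 2 lowest means of all arrays in 14 of the 36 lists. Knockout 12 had means of -0.79 for endothelium, -0.55 for cartilage matrix and chondrocyte regulators, -0.46 for limb patterning factors, -0.45 for skeletal muscle and -0.44 for the Wnt pathway, and a high interferon response mean of 0.37. On the second principal component, which held 22.1% of the variance, these arrays lay at -54.6 and -32.9, and no other array was below -14.0. The liver and trunk list was highest in knockout 9 (0.53), wild-type 2 (0.52) and wild-type 1 (0.41). Deviations from the group means correlated across genes, which are not independent replicates, at 0.81 between wild-type 3 and knockout 5, at 0.70 between knockout 8 and knockout 11, at 0.66 between wild-type 8 and knockout 1, at 0.58 between wild-type 7 and knockout 11 and at 0.54 between wild-type 1 and knockout 12.

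The first pattern is the 4 genes past the threshold. Of 100 splits of the arrays into 9 and 13, 1 gave as many genes, the real one, and the highest other split gave 1. This argues against a random grouping for the count of 4. That count includes Chsy1, which the real split calls by design, and the splits did not keep the layout of positions. The splits therefore did not test the other 3 genes apart. For Grb14, Pcolce2 and Ptx3, the median difference was -0.39 over all arrays, -0.38 with the Y-linked covariate and -0.37 within position 2. All 3 intervals excluded 0 with the covariate and with the position block. These genes were picked for a small p on the same arrays, which favours such intervals. The Y-linked covariate took little off the median, which argues against sex as the whole cause. Position stays undecided: the block rests on the 3 wild-type and 3 knockout arrays of position 2, knockout 1 and wild-type 8 among them. The calls of the 3 genes ended with the covariate and with the block. For Grb14 the estimate went from -0.40 (SE 0.063) to -0.39 (SE 0.066) with the covariate and to -0.37 (SE 0.115) with the block. A smaller estimate and a larger error both raised its p. A lower level in the knockout limb may account for the 3 falls, as a hypothesis only, since these genes were picked for their difference on the same arrays and litter and stage were not tested.

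The second pattern is the 10 lists past the threshold. Chance cannot be excluded for their number: 37 of the 100 splits gave at least 10, and the highest other split gave 20, which points to structure among the arrays. With position on the slide as a block, 4 of the 10 kept their call and direction and 7 other lists gained one, in a contrast of 3 arrays against 3. The 4 include the chondroitin sulfate synthesis list with Chsy1 in it. Of the 7, the unfolded protein response and macrophages were up. Cartilage matrix and chondrocyte regulators, lysosomal breakdown, tendon, proteoglycan core proteins and the hedgehog pathway were down. For shared variation in maturity, read from the skeletal muscle list, 7 of the 9 other lists kept their call with the muscle mean as a covariate (osteoblasts at an adjusted p of 0.046), those of the fibrillar matrix and chondroitin sulfate synthesis ended, and 5 other lists gained one. Since calls of this kind arise in other splits too, calls that stay or end decide neither, and position, maturity and an effect of genotype on these lists all stay open.

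The third pattern is the Chsy1 ratio of sample to reference in the array labelled knockout 1, at 33.6% of the wild-type mean. The smaller of its Xist and Y-linked shares of the highest array was 0.280, where 20 other arrays, all but wild-type 8, had shares of 1.10% to 16.9%. This is consistent with RNA of more than one embryo, for example a knockout and a wild-type embryo of different sex, and argues against a single heterozygous embryo. In wild-type 8 the smaller share was 21.6%, so a similar mixture there stays open. Its Chsy1 ratio was 89.4% of the wild-type mean, and its deviations correlated with those of knockout 1 at 0.66 across genes. Neither value decides on a mixture, since wild-type 3 had a Chsy1 ratio of 73.2% and correlated with knockout 5 at 0.81. Whether any mixture arose at dissection, pooling or hybridisation was not tested.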
